A study of Macaca mulatta with 40 samples.

How the data were processed

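RNA was measured by sequencing in CD4 T cells sorted from the spleens of 10 rhesus macaques, 5 uninfected and 5 infected with simian immunodeficiency virus (SIV) for 24 weeks. The labels name 4 populations: follicular regulatory T cells (TFR), follicular helper T cells (TFH), regulatory T cells (TREG) and bulk CD4 T cells (CD4). Each animal gave each population, which makes 40 libraries in 8 groups of 5. Per the labels, RNA came from a column kit for small samples, full-length complementary DNA from the SMARTer HV kit, and indexed libraries from Nextera XT. Reads were 100 bases long, from 1 end, on an Illumina HiSeq.

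The authors aligned the reads with STAR 2.3.0e and quantified them with Cufflinks and Cuffdiff 2.1.1. The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the mapped reads of the library) for 15845 genes in the 40 libraries. The genome build and the annotation are not given in the sources used here, so genes are named by the symbols in the table and no positions are printed. An Ensembl identifier was found for 13630 of the symbols (86.0%). In 4 column names the animal is spelled differently from its sample titles; these columns were matched to the samples of the remaining animal. Within each status the animals are called replicates 1 to 5, in the order of the sample titles.

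Read counts were not used here, so the depth of each library is unknown in reads and no counting interval or floor was computed. A relative depth was read from the values themselves. Ratios of a gene's low values (FPKM under 2) between libraries piled up at shared steps in 32 libraries of 8 animals. Relative depth in these 32 libraries ran from 0.56 to 1.6, a 2.86-fold range, and 94.6% of 496 library pairs gave the same step within 0.02 on the log2 scale. In uninfected replicate 1 and infected replicate 1 the fullest bin (width 0.005) held 0.82% and 0.83% of low values, against 4.76% to 6.56% in the remaining 8 animals. These 2 animals are treated as a separate batch, and results within the animals that share read steps are given beside the pooled ones. Infection comparisons then hold 8 animals. Population comparisons within 1 status lose replicate 1 of that status, so there this is the same fit as leaving out replicate 1. The number of genes at FPKM 1 or more ran from 4460 to 8952 (median 7965.5). Fewer than 6000 such genes were found in 2 libraries, called sparse here: TFR of uninfected replicate 4 (5067) and TFR of infected replicate 4 (4460).

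Values were taken as log2(FPKM + 1). Genes at FPKM 1 or more in at least 5 libraries of a fit were tested with limma 3.58.1 in R 4.3.3 (linear models with a moderated statistic and an intensity trend). A gene is called at a Benjamini-Hochberg adjusted p under 0.05. Population comparisons used the 20 libraries of one status with the animal as a block, since each animal gave every population. This fit takes 1 spread per gene over the 4 populations. Infection comparisons used the 10 libraries of one population, 5 against 5, without a block. The difference of the infection effect between populations was fitted on all 40 libraries with animal, population and the population-by-infection term. B2M was left out: it is listed at 0 in all 5 uninfected CD4 libraries and at 12889 to 50731 FPKM in the other 35, which marks failed estimates.

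The 21 lists of genes, written before the data were examined, were tested with camera from limma at its preset correlation of 0.01 and again with the correlation estimated per list. They are: Tfh program, Treg program, naive and central memory T cell, Th1 and cytotoxic, Th17 and Th2, interferon-stimulated genes, cell cycle, immediate early and activation, IL-2 and STAT5 signalling, TGF-beta signalling, TNF superfamily costimulation and NF-kB, coinhibitory receptors, apoptosis, trafficking receptors, oxidative phosphorylation and glycolysis, B cell and plasma cell markers, myeloid and dendritic cell markers, CD8 T cell and NK cell markers, red cell, platelet and stromal markers, SIV entry and restriction, and ribosomal protein genes. Lists with fewer than 3 genes tested in a comparison were skipped there. For each list, called genes are counted over all genes tested and adjusted over the list alone. A hypoxia response list and a heat shock response list were written after the largest infection effects had been seen, and their scores use only members not seen before.

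The position of TFR between TREG and TFH was computed per animal. Genes called between TFH and TREG with at least a 2-fold difference were chosen in animals of the other status. The mean TFR minus TREG difference over these genes, signed towards TFH, was divided by the mean TFH minus TREG difference, so that 0 is the TREG level and 1 the TFH level. Status groups were compared by an exact two-sided permutation test over 252 assignments of 5 against 5, whose smallest p is 0.007937.

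Genes named in the text follow a rule fixed before the data were examined. It takes the 10 called genes with the largest increase and the 10 with the largest decrease per comparison. These need a mean of at least 5 FPKM in the higher group and the same direction in all 5 animals, or no overlap between statuses in infection comparisons. Immunoglobulin and T cell receptor segments and ribosomal protein genes are left out of this part. It adds the 4 members with the smallest p of each called list. FOXP3, IL2RA, CTLA4, CXCR5, BCL6, PDCD1, ICOS, IL21, PRDM1, CD4 and MKI67 are always included, with IFI27, ISG15, MX1 and IFIT3 in infection comparisons. Comparisons in infected animals and those against CD4 are limited to 12 genes, and where fewer than 5 genes are called the 5 with the smallest p are named. This gave 504 pairs of gene and comparison over 247 genes, of which the text names a part.

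Alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, median-ratio scaling, array weights, no block, a fit of only the 2 populations compared, 1 fit of all 40 libraries with the animal as a random block, leaving out each animal in turn, and changes to the position measure. Chosen after seeing the data were fits without the sparse libraries, without the 2 animals lacking the shared read steps, without either, and with the read-step batch as a term. The tests were checked on simulated data: 5 simulations with 200 changed genes each, drawn from the real group means and spreads. Changes were put only in the more abundant genes, and the spread was drawn as independent normal values for each gene. Recovery in low genes, and errors shared between genes or within a sparse library, were therefore not checked. Changes of 1, 2 and 3 on the log2 scale were recovered in 20%, 61.8% and 87% of cases for TFR against TFH in uninfected animals, with 4.9% false calls. For infection in TFH 9%, 65.1% and 90.9% were recovered (3.9% false), and for infection in TFR 1.5%, 13.7% and 38.2% (3.8% false). For the difference of the infection effect between TFR and TFH 3.6%, 27.5% and 56.7% were recovered, with 5.5% false calls. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.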

Results

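Gene expression was measured in TFR, TFH, TREG and bulk CD4 T cells sorted from the spleens of 5 uninfected and 5 SIV-infected rhesus macaques, with 5 libraries in each of the 8 groups. TFR are regulatory T cells found with TFH, the helper cells of B cell follicles. Values are FPKM as deposited, given as mean ± SD over 5 animals, and changes are log2 differences ± SE from limma. Genes named for the largest changes had to move the same way in 5 of 5 animals, or not overlap between statuses. For them this is no separate evidence. Genes at FPKM 1 or more per library averaged 7288 ± 1266 in uninfected TFR, 7774 ± 564 in TFH, 7567 ± 593 in TREG and 7287 ± 353 in CD4. In infected animals the averages were 7728 ± 1889, 8291 ± 301, 8421 ± 259 and 8047 ± 812 in the same order. The summed FPKM per library ran from 481524 to 948677, and the 10 most abundant genes held 9.16% to 19.1% of it. Depth in reads is unknown.

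Libraries separated more by infection than by population. Without the 2 sparse TFR libraries the first principal component held 16.8% of the variance. Infected libraries lay at -21.3 to 80.2 on it (median 46.8) and uninfected libraries at -79.3 to 0.8 (median -40.3). The statuses overlapped only through the CD4 library of infected replicate 4, at -21.3. The next lowest infected library lay at 3.9. That CD4 library had 6671 genes at FPKM 1 or more, and the libraries of its animal had relative depths of 0.56 to 0.7. The highest correlation between 2 libraries, taken across genes, was 0.891. After removal of the group means, libraries of the same animal correlated across genes with a median r of 0.139 over 60 pairs, against -0.033 over 240 pairs of different animals of one status. The correlation of libraries within an animal that limma estimated over all genes was 0.141.

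**Figure D1:**
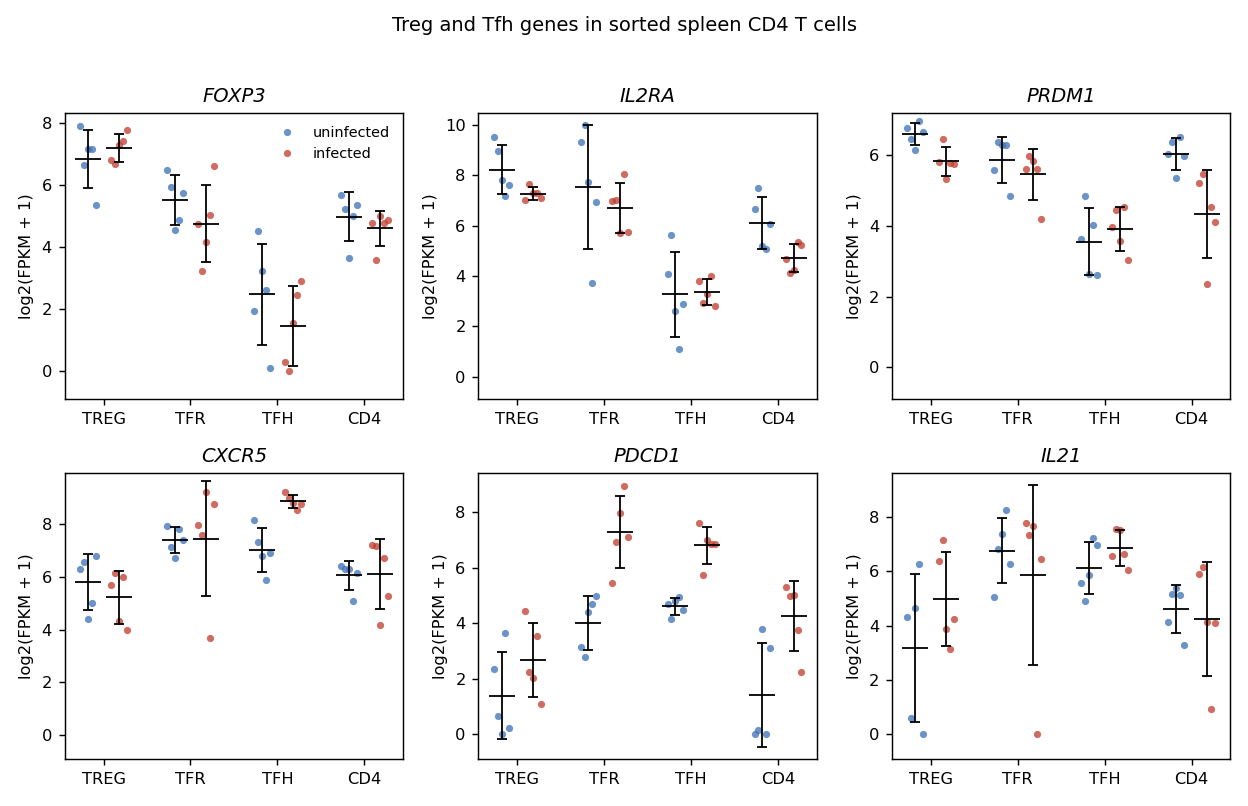
Expression of 6 Treg and Tfh genes as log2(FPKM + 1) in each of the 40 libraries, by population (horizontal axis) and infection status (colour), with the mean and SD of 5 animals. In uninfected animals FOXP3 was 51.0 FPKM in TFR, 7.69 in TFH and 134 in TREG, and CXCR5 was 175, 146 and 66.4.

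The comparison of TFR with TFH in uninfected animals asked what sets the regulatory follicular cells apart from the helper cells. TFR carried the Treg genes IL2RA and PRDM1 and the cyclin gene CCND2 at higher levels, and the cytotoxic transcripts GZMK and NKG7 at lower levels. Of 8930 genes tested, 7 were called, 3 higher and 4 lower in TFR (3 genes when only these populations were fitted), while 552 had an unadjusted p under 0.05 and chance gives 446. IL2RA was higher by 4.28 ± 0.48 (406 ± 429 against 15.5 ± 19.4 FPKM, adjusted p 1.03e-04, higher in 5 of 5 animals). CCND2 rose by 2.71 ± 0.27 (adjusted p 5.15e-05) and PRDM1 by 2.31 ± 0.36 (adjusted p 0.0069), each in 5 of 5 animals. GZMK differed by -6.10 ± 0.68 (0.437 ± 0.759 against 111 ± 83.3 FPKM, adjusted p 1.03e-04) and NKG7 by -4.77 (adjusted p 0.0016). IL7R (-2.82) and TRAT1 (-1.24) were lower with an adjusted p of 0.033 each, and IL7R had an adjusted p of 0.061 without the sparse libraries. FOXP3 was higher in 5 of 5 animals but not called (3.04 ± 0.60, adjusted p 0.071). The Tfh genes CXCR5 (0.39), BCL6 (-0.32), PDCD1 (-0.62), ICOS (0.71), IL21 (0.65) and CTLA4 (0.22) were not called, with CXCR5 from -0.006 to 0.54 when 1 animal was left out. Of the 6 lists called, the Treg program was higher in TFR (camera adjusted p 7.11e-07), with 2 genes called higher over all genes and 5 when adjusted over the list alone. IL-2 and STAT5 signalling was higher too (adjusted p 0.0019, PIM2 1.16 and CISH 1.97 among its 13 genes, 0 called over all genes and 1 adjusted over the list alone). Both calls held with the estimated correlation, at adjusted p 0.034. Th1 and cytotoxic genes were lower (adjusted p 6.79e-06, 0 higher and 2 lower over all genes, 1 higher and 5 lower adjusted over the list alone). Cell cycle genes such as AURKB (2.52) and CDC20 (1.84) were higher as a list (adjusted p 2.32e-06), as were oxidative phosphorylation and glycolysis (0.0017) and ribosomal protein genes (4.94e-08), with 0 genes called in these 3 lists. These 4 calls were lost with the estimated correlation, at adjusted p 0.102, 0.123, 0.102 and 0.776. The Tfh program was not called (adjusted p 0.945). Leaving out replicates 1 to 5 in turn gave 6, 5, 4, 7 and 5 genes. The fit without replicate 1 is also the fit on the uninfected animals sharing read steps. In it IL2RA was at 4.04 (adjusted p 0.0071), CCND2 at 2.86, GZMK at -5.94 and PRDM1 at 2.40 (adjusted p 0.053).

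TFR and TREG of uninfected animals were compared to find which genes differ between these sorted populations. TFR had more IL21, CXCR5, CD200, SH2D1A and TIGIT and less of the receptors S1PR1, CCR7 and CCR6. The test called 144 genes, 62 higher and 82 lower in TFR, but 8 when only these populations were fitted. The largest increases were IGFBP4 (4.51 ± 0.63, 134 ± 37.6 against 5.41 ± 3.22 FPKM, adjusted p 0.0011), SULF2 (4.47), CYB5R1 (3.80), TNS4 (3.70) and CTNNA1 (3.66). The largest decreases were GNLY (-5.02 ± 0.76, adjusted p 0.0020), CCL20 (-4.88), HOPX (-4.46), IL1RL1 (-4.30) and IL7R (-4.24). Each of these 10 genes moved the same way in 5 of 5 animals, as their choice required. HOPX is listed at 0 in all 5 TFR libraries, so its difference is no fold change. The Tfh program was higher (adjusted p 2.95e-11, 5 genes called higher over all genes and 9 adjusted over the list alone). In it, IL21 was higher by 3.58 ± 0.76 (139 ± 105 against 24.3 ± 31.6 FPKM, adjusted p 0.016) and CD200 by 1.97. CXCR5 was 175 ± 57.8 against 66.4 ± 39.2 FPKM (1.59, adjusted p 0.033, and 0.075 without the sparse libraries). PDCD1 (2.62, adjusted p 0.134) and BCL6 (0.71, 0.289) were higher in 5 of 5 animals but not called. Naive and central memory genes were lower (adjusted p 9.65e-06, 4 lower over all genes and 5 adjusted over the list alone), with S1PR1 at -3.71 (adjusted p 0.0298) and CCR7 at -1.66 (0.00927). Th17 and Th2 genes were lower (5.52e-07, 2 and 6 genes), with CCR6 at -2.93. Cell cycle genes were higher (2.95e-11, 0 and 6 genes), with TOP2A at 2.85 and AURKB at 3.85. Oxidative phosphorylation and glycolysis was higher (2.63e-04, 2 genes either way, PKM 0.74 and COX5B 0.88). These 5 calls held with the estimated correlation.

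In the same comparison 8 further lists were called and not held with the estimated correlation. The Treg program was lower in TFR (adjusted p 0.0013 and 0.068 estimated, 1 gene lower over all genes and 6 adjusted over the list alone), and FOXP3 was 51.0 ± 27.1 in TFR against 134 ± 74.1 FPKM in TREG (-1.33, adjusted p 0.345). IL2RA (-0.68), PRDM1 (-0.73), CTLA4 (0.31) and ICOS (0.02) were not called, and IL2RA (-1.11 to 0.021) and ICOS (-0.056 to 0.152) turned sign with 1 animal left out. Lower in TFR were Th1 and cytotoxic genes (0.0132, 2 and 3 genes), immediate early and activation genes (0.0184, 0 and 2), IL-2 and STAT5 signalling (0.045, 1 and 3, PIM1 -2.83) and TGF-beta signalling (0.034, 1 and 2, TGFBR2 -2.26). Trafficking receptors were lower (0.0243, 2 lower over all genes, 1 higher and 3 lower adjusted over the list alone, GPR183 -1.14 and CXCR6 -4.01). Ribosomal protein genes were lower (3.02e-11, 0 genes) and B cell and plasma cell markers higher (0.0149, 0 over all genes and 2 adjusted over the list alone). Their estimated adjusted p were 0.253, 0.127, 0.0802, 0.0683, 0.0775, 0.343 and 0.0611 in this order. The count of called genes was 86, 84, 67, 123 and 35 without replicates 1 to 5, so each animal but replicate 4 changed it by more than 1.5 times. The 86 genes without replicate 1 are also the count for the uninfected animals sharing read steps. In that fit IGFBP4 was at 4.24 (adjusted p 0.018), IL21 at 4.30 (0.025) and CXCR5 at 1.58 (0.12).

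TFH were set against TREG in uninfected animals to place the poles between which TFR lie. TREG carried FOXP3, IL2RA, PRDM1, CCL20 and IL1RL1, and TFH carried CD200, SH2D1A, GZMK, DOK5 and IGFBP4. In this comparison 107 genes were called, 49 higher and 58 lower in TFH, and 68 when only these populations were fitted. FOXP3 was 7.69 ± 8.51 in TFH and 134 ± 74.1 FPKM in TREG (-4.37 ± 0.60, adjusted p 7.34e-04). IL2RA was 15.5 ± 19.4 against 361 ± 251 FPKM (-4.96 ± 0.48, adjusted p 3.0e-05), and CCL20 differed by -6.01 and PRDM1 by -3.04. DOK5 was higher by 4.91 ± 0.88 (adjusted p 0.0062), IGFBP4 by 4.11, CTNNA1 by 3.79 and GZMK by 3.59. All of these moved the same way in 5 of 5 animals, as the choice of the largest changes required. IL21 (2.94, adjusted p 0.067), PDCD1 (3.24, 0.067), BCL6 (1.04, 0.115) and CXCR5 (1.20, 0.148) were higher in 5 of 5 animals without being called, and CTLA4 (0.09) and CD4 (-0.03) were not called either and turned sign with 1 animal left out (-0.038 to 0.255 and -0.124 to 0.083). The Treg program was lower in TFH (adjusted p 4.25e-14, 5 genes lower over all genes and 12 adjusted over the list alone). The Tfh program was higher (6.77e-13, 3 higher over all genes, 15 higher and 1 lower adjusted over the list alone). Naive and central memory genes (3.07e-06, 3 lower over all genes, 1 higher and 6 lower adjusted over the list alone, LEF1 -2.29) and Th17 and Th2 genes (7.76e-10, 5 and 7, IL4R -2.58) were lower. IL-2 and STAT5 signalling was lower (1.27e-06, 2 and 5, PIM2 -1.72). B cell and plasma cell markers were higher (1.10e-04, 2 and 3 of 4 genes), with IGJ at 81.9 ± 82.2 against 5.41 ± 12.1 FPKM and CR2 at 1.84. MS4A1 and CD22 were under 1.3 FPKM on average in each of these groups. These 6 calls held with the estimated correlation. Lost with it were interferon-stimulated genes (lower, adjusted p 0.0062 and 0.264 estimated, IFI27 -3.02), cell cycle (higher, 0.0017 and 0.218), immediate early and activation (lower, 0.0082 and 0.0995, TNFAIP3 -1.83) and TGF-beta signalling (lower, 0.0238 and 0.0599). TNF superfamily costimulation and NF-kB (lower, 0.0238 and 0.218), trafficking receptors (lower, 0.0195 and 0.076) and ribosomal protein genes (lower, 5.31e-32 and 0.0995, RPS14 -0.94) were lost too. In these 7 lists, 1, 0, 1, 0, 0, 0 and 4 genes were called over all genes and 4, 0, 2, 0, 3, 3 and 39 adjusted over the list alone, in the stated direction. Without replicates 1 to 5 in turn 64, 58, 30, 99 and 29 genes were called. The 64 genes without replicate 1 are also the count for the uninfected animals sharing read steps, with FOXP3 at -3.96 (adjusted p 0.017) and IL2RA at -4.84.

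Bulk CD4 cells of uninfected animals served as the reference for each sorted population. Cytotoxic transcripts were lower in each of the 3 sorted populations. Against CD4, 201 genes were called in TFR (94 higher, 107 lower), 105 in TFH (38 higher, 67 lower) and 2 in TREG, both lower. With only the compared populations in the fit the counts were 30, 44 and 6. GZMK was 242 ± 163 FPKM in CD4 and 0.437 ± 0.759 in TFR (-7.31 ± 0.68, adjusted p 5.77e-06), and GNLY differed by -7.30. In TREG, NKG7 (-5.13, adjusted p 0.0022) and GZMK (-4.80, adjusted p 0.0040) were the called genes, and TNFRSF9 (3.66, 0.0542), CCR6 (3.21) and COA1 (-0.95) had the next smallest p. TFR exceeded CD4 in TNFRSF9 (3.90, adjusted p 0.0032), the cell cycle genes MCM4 (3.94) and RRM2 (3.66), and in CENPM (4.53). TFH exceeded CD4 in DOK5 (4.28, adjusted p 0.020), ADORA2A (3.56), PTGER2 (3.45) and IGFBP4 (3.17). The Th1 and cytotoxic list was lower in TFR (adjusted p 5.50e-15, 7 genes over all genes and 14 adjusted over the list alone), TFH (1.33e-08, 3 and 6) and TREG (1.05e-16, 2 and 11). The Tfh program was higher in TFR (6.60e-09, 5 and 13) and TFH (1.02e-10, 5 and 11), and the Treg program in TREG (1.43e-11, 0 and 9). Naive and central memory genes were lower in TFR (8.27e-05, 3 and 5) and TFH (6.01e-06, 3 and 4), and trafficking receptors in TFR (0.0065) and TFH (0.0023). Cell cycle genes were higher in TFR (5.74e-10, 3 and 9). Th17 and Th2 (4.22e-06), IL-2 and STAT5 signalling (0.015) and ribosomal protein genes (7.78e-59, 20 and 72 lower) were lower in TFH. IL-2 and STAT5 signalling was higher (0.0040) and B cell markers lower (0.0031) in TREG. All of these list calls held with the estimated correlation, and the 8 further calls did not. Leaving out replicates 1 to 5 gave 73, 72, 134, 159 and 60 genes for TFR, 17, 58, 37, 62 and 13 for TFH, and 2, 1, 3, 4 and 0 for TREG. The counts without replicate 1 (73, 17 and 2) are also those of the uninfected animals sharing read steps.

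In infected animals the populations were compared again, with the same questions. FOXP3 and IL2RA were called between TFR and TFH, and PDCD1, CD200 and FOXP3 between TFR and TREG, but no gene (0) was called in either when only these populations were fitted. Of 9549 genes, limma called 2 between TFR and TFH, 11 between TFR and TREG (5 higher, 6 lower) and 44 between TFH and TREG (21 higher, 23 lower, and 95 genes with only these populations fitted). Unadjusted p under 0.05 were found for 804, 981 and 666 genes, where chance gives 477. Between TFR and TFH, IL2RA was 126 ± 88.8 against 9.86 ± 3.93 FPKM (3.34 ± 0.41, adjusted p 0.0013) and FOXP3 36.0 ± 35.1 against 2.68 ± 2.85 FPKM (3.30 ± 0.46, adjusted p 0.0046). CTSH, CCND2 and TCF7 had the next smallest p (adjusted p 0.0861, 0.109 and 0.110) and were not called. Between TFR and TREG, PDCD1 was 209 ± 176 against 7.85 ± 8.0 FPKM (4.62 ± 0.66, adjusted p 0.0066). APOD (3.95), CD200 (1.84), CA6 (-4.74), FOXP3 (-2.45) and CCR7 (-2.03) were called as well. TFH exceeded TREG in PDCD1 (4.15), CXCR5 (470 ± 83.5 against 43.2 ± 25.0 FPKM, 3.64, adjusted p 0.0389), TSPAN12 (5.60) and APOD (3.81), and had less FOXP3 (-5.75 ± 0.46, adjusted p 1.71e-06). Every called gene named here moved the same way in 5 of 5 animals, as the choice of the largest changes required. The Treg program was higher in TFR than TFH (adjusted p 4.03e-06, 2 genes over all genes and 3 adjusted over the list alone), as was Th17 and Th2 (4.34e-04, 0 and 2). TFR had more of the Tfh program than TREG (4.61e-14, 2 and 13), less of the Treg program (7.73e-04, 1 lower over all genes, 1 higher and 6 lower adjusted over the list alone) and less of the naive list (4.93e-06, 1 and 6). Between TFH and TREG the Tfh program was higher (7.07e-30, 5 and 17), the Treg program lower (6.68e-18, 4 lower over all genes, 1 higher and 14 lower adjusted over the list alone) and Th17 and Th2 lower (2.39e-06, 1 and 5). These 8 list calls held with the estimated correlation. Lost with it were 8 calls between TFR and TFH, among them the Tfh program (lower, 0.0114 and 0.309 estimated) and CD8 T cell and NK cell markers (higher, 0.0188 and 0.271), and 4 in each of the other comparisons. Without replicates 1 to 5 limma called 1, 0, 1, 5 and 1 genes between TFR and TFH, 5, 1, 0, 31 and 6 between TFR and TREG, and 16, 8, 5, 88 and 12 between TFH and TREG. The larger counts came without replicate 4, the animal of a sparse library. The counts without replicate 1 (1, 5 and 16) are also those of the infected animals sharing read steps.

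The place of TFR between TREG and TFH was compared between statuses in each animal. TFR lay nearer to TFH than to TREG on average in both statuses. The position was 0.781 ± 0.168 in uninfected and 0.720 ± 0.178 in infected animals (n = 5 each), a difference of -0.061 with an exact permutation p of 0.595. The position rests on 44 genes in uninfected and 100 in infected animals, chosen in the other status. The statuses were thus measured on different genes, which the permutations did not choose again. The test therefore cannot tell a shift of TFR, or its absence, from a difference between the gene sets. For genes higher in TFH the positions were 0.939 ± 0.062 and 0.805 ± 0.165 (exact permutation p 0.135), and for genes higher in TREG 0.640 ± 0.271 and 0.676 ± 0.304 (exact permutation p 0.841). For genes higher in TREG the sparse libraries gave the highest position of each status (1.062 and 1.06). The other animals ran from 0.312 to 0.668 in uninfected and from 0.329 to 0.865 in infected animals. Without the sparse libraries the position over all chosen genes was 0.785 and 0.686 (exact permutation p 0.371). Leaving out infected replicate 1 or 3 changed the sign of the difference, to 0.054 and 0.122. The difference was 0.006 within the 8 animals sharing read steps (exact permutation p 1).

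**Figure D2:**
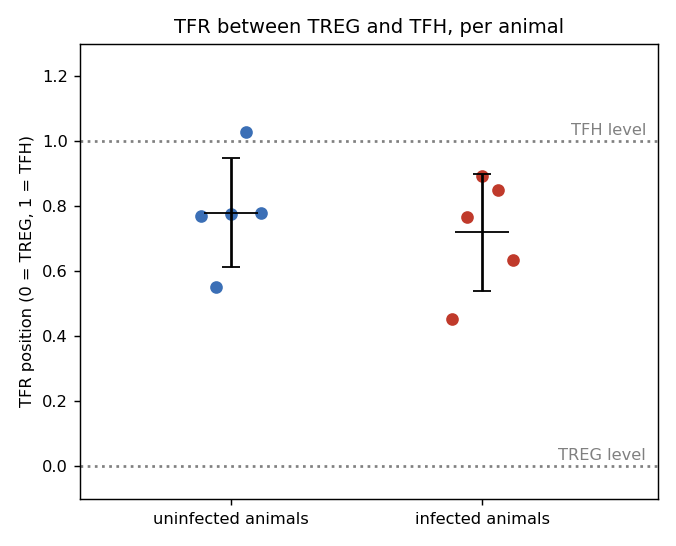
Position of TFR between the TREG level (0) and the TFH level (1) for each of 5 uninfected and 5 infected animals, with mean and SD. Values ran from 0.553 to 1.03 in uninfected and from 0.453 to 0.893 in infected animals.

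Infection was examined in each population by comparing 5 infected with 5 uninfected animals. The median difference over all genes was 0.10 in TFR, 0.18 in TFH, 0.25 in TREG and 0.22 in CD4 as deposited, and -0.08, -0.03, -0.01 and -0.05 after quantile normalization, so changes are relative to these shifts. In TFR, genes induced by low oxygen or heat were lower in infected animals (ANKRD37, HSPA1A, HILPDA, BNIP3), and CD52, ACTB and S100A4 were higher. Of 8099 genes 25 were called, 10 higher and 15 lower, with 831 at an unadjusted p under 0.05 where chance gives 405. Array weights gave 253 genes, and a fit of all 40 libraries with the animal as a random block 423. ANKRD37 was 1.97 ± 2.17 in infected and 392 ± 204 FPKM in uninfected TFR (-7.25 ± 0.72, adjusted p 2.09e-04). HSPA1A (-6.64), HILPDA (-6.06), PFKFB4 (-5.50), BNIP3 (-5.44) and SLC2A3 (-4.07) fell as well. CD52 rose by 2.36 ± 0.27 (adjusted p 7.74e-04), ACTB by 1.60, S100A4 by 3.92, PTPN6 by 2.46 and MAMU-DRA by 6.47 (467 ± 387 against 6.40 ± 11.4 FPKM). All infected animals lay on one side of all uninfected animals for each of these genes, as the choice of the largest changes required. PDCD1 was 209 ± 176 against 17.8 ± 10.6 FPKM (3.29, adjusted p 0.0722) and not called. FOXP3 (-0.77), IL2RA (-0.84), CTLA4 (-0.49), CXCR5 (0.06), BCL6 (-0.56), ICOS (-1.30), IL21 (-0.91), MKI67 (1.93) and CD4 (1.35) were not called, nor were IFI27 (4.43), ISG15 (1.90), MX1 (2.66) and IFIT3 (-0.72). Leaving out 1 animal turned the sign of CTLA4 (-0.79 to 0.249), CXCR5 (-0.381 to 0.999), IL21 (-1.394 to 0.555) and IFIT3 (-1.695 to 0.117). The list tests called Th1 and cytotoxic (higher, adjusted p 0.0011, 0 genes over all genes and 4 adjusted over the list alone, PRF1 3.78), cell cycle (higher, 1.05e-08, 0 and 9, UBE2C 3.80), oxidative phosphorylation and glycolysis (lower, 0.0231, 1 and 5) and ribosomal protein genes (lower, 0.0357, 0 and 0). With the estimated correlation none held, at adjusted p 0.538, 0.538, 0.538 and 0.776. Without the sparse libraries 161 genes were called. Leaving out uninfected replicates 1 to 5 gave 11, 20, 11, 18 and 11 genes, and infected replicates 1 to 5 gave 20, 15, 19, 96 and 16, the 96 without the animal of a sparse library. Within the 8 animals sharing read steps 5 genes were called (ANKRD37 -7.35, adjusted p 0.0049, CD52 2.28, adjusted p 0.011), and 34 when the sparse libraries were left out as well.

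In TFH, infected animals had more PDCD1, CXCR5, TOX2, IL6R and SLAMF6, with the same hypoxia and heat shock genes lower. Of 8309 genes 452 were called, 246 higher and 206 lower, and 226 in the fit of all 40 libraries. After quantile normalization 193 were higher and 247 lower. CXCR5 was 470 ± 83.5 against 146 ± 84.6 FPKM (1.85 ± 0.35, adjusted p 0.0058), PDCD1 121 ± 50.9 against 24.0 ± 5.02 FPKM (2.20 ± 0.36, adjusted p 0.0023) and CD4 305 ± 41.1 against 82.7 ± 37.2 FPKM (2.01, adjusted p 0.0029). TOX2 rose by 2.38, IL6R by 1.75 and SLAMF6 by 1.84. PLAC8 (4.84), MAMU-DMA (4.48), S100A4 (4.24) and CDC20 (4.14) were among the largest increases. ANKRD37 (-7.34 ± 0.48, adjusted p 4.10e-07), HSPA1A (-6.67), CGA (-5.64), SYTL3 (-5.45), HILPDA (-5.09) and TNFRSF9 (-4.74) were the largest decreases. For all of these genes the statuses did not overlap, as the choice of the largest changes required. B cell transcripts averaged higher in infected TFH as well, with CD79A at 114 ± 38.2 against 28.5 ± 28.2 FPKM and CD79B at 17.4 ± 22.6 against 0.112 ± 0.170. MS4A1 averaged 16.4 ± 22.4 against 0 FPKM, with 3 infected libraries at 0, and CR2 was not higher (49.5 against 54.5). CD79A also averaged higher in infected TFR, TREG and CD4. Whether B cell RNA adds to increases such as that of MAMU-DMA was not tested. BCL6 (-0.78), ICOS (0.65), IL21 (0.74), FOXP3 (-1.03), IL2RA (0.09), PRDM1 (0.35), CTLA4 (0.42) and MKI67 (1.37) were not called, and IL2RA turned sign when 1 animal was left out (-0.45 to 0.685). Of the 4 lists called, the Tfh program, interferon-stimulated genes, cell cycle, and oxidative phosphorylation and glycolysis, none held with the estimated correlation (adjusted p 0.0814, 0.637, 0.547 and 0.351). At the preset correlation the Tfh program was higher (adjusted p 1.02e-04, 9 genes higher over all genes, 11 higher and 1 lower adjusted over the list alone), as were interferon-stimulated genes (0.0027, 1 and 1, LY6E 3.31) and cell cycle (2.47e-04, 4 and 7). In the interferon list IFI27 (5.78, adjusted p 0.0577), ISG15 (-0.01), MX1 (1.04) and IFIT3 (1.26) were not called, and ISG15 ran from -0.633 to 1.57 with 1 animal left out. Oxidative phosphorylation and glycolysis was lower (0.0035, 7 lower over all genes, 1 higher and 11 lower adjusted over the list alone). Its mean was -0.47 and its median 0.07, since LDHA (-2.31), GAPDH (-1.62) and PGK1 (-1.65) fell and most members did not. Without uninfected replicates 1 to 5 the counts were 338, 572, 264, 250 and 231, and without 1 infected animal they ran from 211 (replicate 3) to 466 (replicate 4). Infection gave 173 called genes within the 8 animals sharing read steps, with CXCR5 at 2.05 (adjusted p 0.0049), PDCD1 at 2.02 (0.016) and ANKRD37 at -7.07.

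In TREG, infected animals had less BCL6 and CCL20, more CXCR3 and SAMHD1, and more of several cell cycle genes. Of 8264 genes 398 were called, 211 higher and 187 lower, and 246 in the fit of all 40 libraries. After quantile normalization 153 were higher and 201 lower. BCL6 was 7.99 ± 4.81 against 44.4 ± 9.90 FPKM (-2.51 ± 0.50, adjusted p 0.0107) and CCL20 8.84 ± 7.56 against 499 ± 224 FPKM (-6.11 ± 0.64, adjusted p 9.55e-05). HSPA1A (-7.73), C15orf48 (-6.66), ANKRD37 (-5.78), HILPDA (-5.38) and DNAJB1 (-4.38) were lower. CXCR3 was higher by 4.80 ± 0.76 (adjusted p 0.0028), CD79A by 4.31, SAMHD1 by 2.31 and CD4 by 1.53. For these genes the statuses did not overlap, as the choice of the largest changes required. FOXP3 (0.35), IL2RA (-0.96), CTLA4 (0.43), ICOS (-0.69), PRDM1 (-0.77), CXCR5 (-0.59), PDCD1 (1.29), IL21 (1.79) and MKI67 (2.29, adjusted p 0.0533) were not called. The estimated correlation left 0 of 9 list calls, with adjusted p of 0.139 or more. At the preset correlation the called lists were cell cycle (higher, adjusted p 1.45e-07, 5 genes over all genes and 19 adjusted over the list alone, HMMR 3.06 and BUB1 3.19) and interferon-stimulated genes (higher, 0.0112, 3 higher and 1 lower over all genes, 5 and 1 adjusted over the list alone). In the latter OAS3 (2.65), OAS1 (2.92) and IFI27 (4.36) rose and PARP12 (-1.61) fell, and ISG15 (-0.15), MX1 (2.21) and IFIT3 (0.00) were not called. With 1 animal left out FOXP3 (-0.017 to 0.621), ISG15 (-0.716 to 0.697) and IFIT3 (-0.339 to 0.37) turned sign. SIV entry and restriction genes were higher (0.0373, 2 higher over all genes, 3 higher and 1 lower adjusted over the list alone). Th17 and Th2 (0.0038, 2 and 2, IL4R -1.44), IL-2 and STAT5 signalling (0.0332, 2 and 2, SOCS3 -2.39), TGF-beta signalling (0.0014, 1 and 1, ID3 -1.24) and apoptosis (0.0383, 1 and 1, PMAIP1 -2.32) were lower. TNF superfamily costimulation and NF-kB was lower (0.0298, 1 higher over all genes, 1 higher and 2 lower adjusted over the list alone, LTB 1.90), as were ribosomal protein genes (9.09e-04, 1 and 0 lower). Without uninfected replicates 1 to 5 there were 337, 344, 310, 220 and 234 called genes, and without infected replicates 1 to 5 there were 190, 154, 203, 545 and 192. There were 139 called genes within the 8 animals sharing read steps, with BCL6 at -2.54 (adjusted p 0.044) and CCL20 at -6.31 (adjusted p 0.0013).

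In bulk CD4 cells, infected animals had less KLRB1, GNLY and CCL20 and more CD4. Of 7998 genes 283 were called, 138 higher and 145 lower, against 468 in the fit of all 40 libraries and 543 with array weights. After quantile normalization 88 were higher and 163 lower. KLRB1 was 16.8 ± 26.9 against 407 ± 235 FPKM (-5.66 ± 0.89, adjusted p 0.0036), GNLY 91.5 ± 92.7 against 659 ± 188 FPKM (-4.32, adjusted p 0.0428) and CD4 266 ± 50.4 against 79.9 ± 24.5 FPKM (1.76, adjusted p 0.0079). HSPA1A (-8.19 ± 0.63, adjusted p 1.33e-05), HILPDA (-6.66), C15orf48 (-6.21), DNAJB1 (-5.77) and ANKRD37 (-5.71) fell. EDARADD (4.69), CDKN3 (4.50) and PSTPIP1 (4.27) rose, and TMED1 is listed at 0 in the uninfected libraries. For these genes the statuses did not overlap, as the choice of the largest changes required. CCL20 was 18.2 ± 25.6 against 173 ± 130 FPKM (-4.37, adjusted p 0.0308). FOXP3 (-0.38), IL2RA (-1.38), CTLA4 (0.11), CXCR5 (0.05), BCL6 (-2.16), PDCD1 (2.85), ICOS (-0.90), IL21 (-0.38), PRDM1 (-1.71) and MKI67 (1.05) were not called, nor were IFI27 (2.73), ISG15 (-0.66), MX1 (1.52) and IFIT3 (-1.73). The sign turned with 1 animal left out for CTLA4 (-0.188 to 0.415), CXCR5 (-0.223 to 0.529), IL21 (-0.858 to 0.454) and ISG15 (-1.278 to 0.077). With the estimated correlation 0 of 7 list calls held (adjusted p 0.161 or more). At the preset correlation, lists lower in infected animals were ribosomal protein genes (adjusted p 9.09e-23, 6 genes lower over all genes, 1 higher and 33 lower adjusted over the list alone, RPS16 -1.48) and oxidative phosphorylation and glycolysis (0.0011, 6 and 7, LDHA -2.80). Th1 and cytotoxic (0.0043, 1 lower over all genes, 1 higher and 3 lower adjusted over the list alone), Th17 and Th2 (0.0043, 2 and 3), apoptosis (0.0258, 3 lower over all genes, 1 higher and 4 lower adjusted over the list alone) and TGF-beta signalling (0.0433, 0 and 1) were lower too. Cell cycle was higher (0.0240, 1 and 1, PLK1 4.02). Counts were 161, 179, 155, 137 and 104 without uninfected replicates 1 to 5, and 220, 186, 116, 306 and 137 without infected replicates 1 to 5. The 8 animals sharing read steps gave 125 called genes, with KLRB1 at -6.38 (adjusted p 0.0042) and CD4 at 1.69 (0.034).

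**Figure D3:**
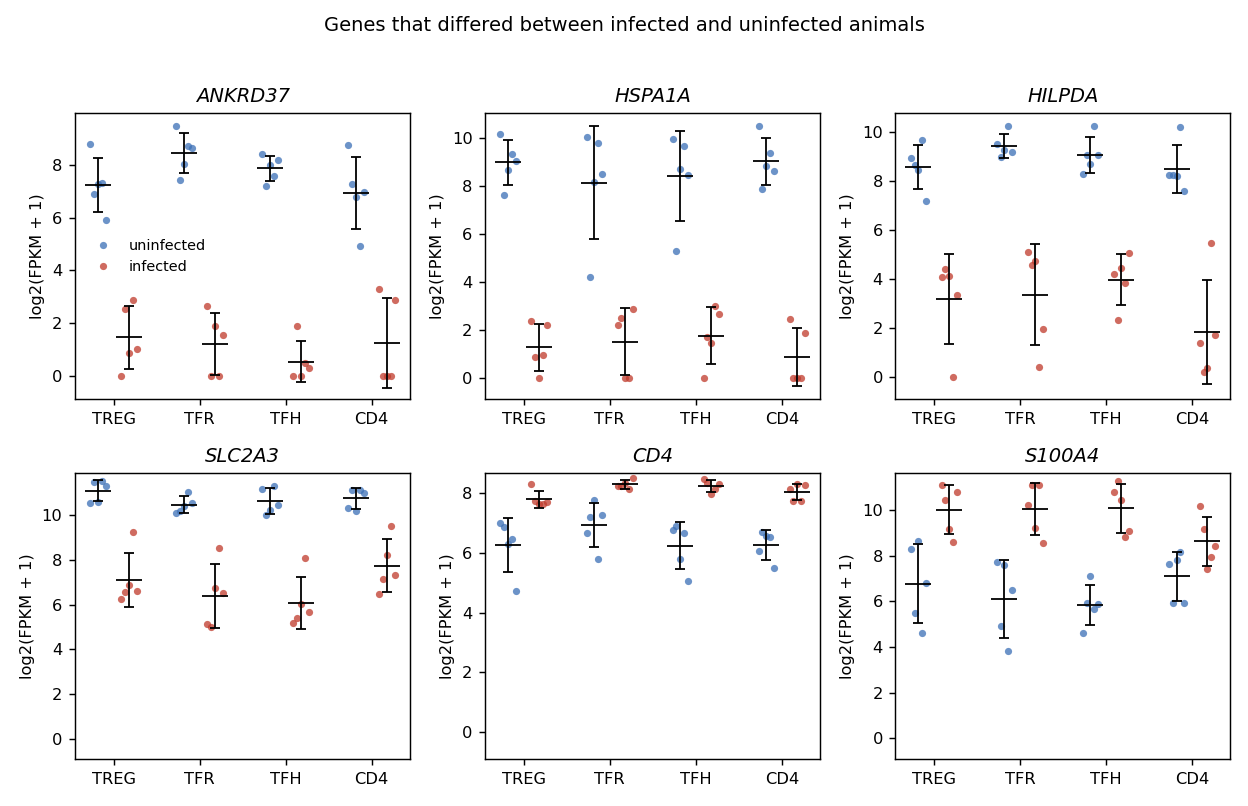
Expression of 6 genes called for infection in at least 1 population, as log2(FPKM + 1) in each of the 40 libraries, by population (horizontal axis) and infection status (colour), with the mean and SD of 5 animals. ANKRD37 averaged 392 FPKM in uninfected and 1.97 in infected TFR, and CD4 averaged 82.7 in uninfected and 305 in infected TFH.

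Part of the infection effect was shared between populations. Of 452 genes called in TFH and 398 in TREG, 159 were shared in the same direction, 63 higher and 96 lower, where independent calls give 5.69 and 4.72. TFH, TREG and CD4 shared 91 (29 higher and 62 lower, with 0.09 and 0.09 given by independence), and all 4 populations shared 16 (4 higher and 12 lower). The populations come from the same animals, so these calls are not independent. A hypoxia response score over 39 genes not seen beforehand, averaged over the 4 libraries of each animal, was 4.14 ± 0.19 in infected and 5.22 ± 0.24 in uninfected animals. The difference was -1.08 with an exact permutation p of 0.00794, the smallest that assignments of 5 against 5 give. It was -1.29 in TFR, -1.22 in TFH, -0.88 in TREG and -0.92 in CD4, and 34 of the 39 genes were lower. Of the 39 genes, 9 are also in the oxidative phosphorylation and glycolysis list, which was itself tested for infection. The remaining 30 differed by -1.11 (exact permutation p 0.00794). Heat shock genes not seen beforehand were lower in 16 of 16 cases, with scores of 5.03 ± 0.17 and 6.69 ± 0.51 (exact permutation p 0.00794). The other members of the oxidative phosphorylation and glycolysis list, 20 genes, differed by 0.18 (exact permutation p 0.429), and all 10102 genes by 0.25 (0.0714). The hypoxia score within the 8 animals sharing read steps differed by -1.03 (exact permutation p 0.0286, the smallest that 70 assignments give). How tissue and cells were handled in each status is not given in the sources used here.

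Whether infection acted differently on TFR than on TFH or TREG was tested with the difference of the infection effects. Limma called 0 of 10102 genes for TFR minus TFH and 0 for TFR minus TREG, with 504 and 671 at an unadjusted p under 0.05 where chance gives 505. In simulated data the test of TFR minus TFH recovered 3.6%, 27.5% and 56.7% of differences of 1, 2 and 3, so 0 calls do not show equal effects. The 5 smallest p for TFR minus TFH belonged to ABHD12B, HIST1H3J, GZMK, DTX3L and NPC1 (adjusted p 0.413 to 0.705). For TFR minus TREG they belonged to UAP1, UTP6, CPPED1, MFSD3 and TMEM161A (0.296 to 0.449). The list tests called 3 differences, which were lost with the estimated correlation (adjusted p 0.480, 0.440 and 0.0989). At the preset correlation the Th1 and cytotoxic list moved higher in TFR than in TFH (median 1.05, adjusted p 0.0025, 0 genes over all genes and 1 adjusted over the list alone) and than in TREG (median 0.66, adjusted p 0.0359, 0 and 0). Th17 and Th2 moved higher in TFR than in TREG (median 0.90, adjusted p 0.0022, 0 and 1, CTSH 4.03). Leaving out infected replicate 4, the animal of a sparse library, gave 2 and 1 genes, and leaving out any other animal gave 0. No gene (0) was called in either test within the 8 animals sharing read steps. The lists for coinhibitory receptors, myeloid and dendritic cell markers, and red cell, platelet and stromal markers passed in no comparison in which they were tested, and their smallest adjusted p were 0.104, 0.0542 and 0.243.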

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

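The tests of B cell transcripts, of the sparse libraries and of regrouped libraries were chosen only after their results had been seen. The tests of the hypoxia genes and of a smaller infection effect in TFR were fixed before their results were seen, on a pattern noticed in the data.

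The first pattern is the lower expression of hypoxia response genes in infected animals, seen in ANKRD37, HILPDA, BNIP3 and PFKFB4. It was then tested on 39 genes not among those seen. Of these, 9 are also in the oxidative phosphorylation and glycolysis list, whose infection tests drew on them too. The remaining 30 differed by -1.111 (exact permutation p 0.00794). Scaling between libraries as the whole cause is argued against by quantile normalization, which left a difference of -1.26 (exact permutation p 0.00794). The read-step batch holds 1 uninfected and 1 infected animal, so a shift common to both could not lower the score in infected animals. The 8 animals that share read steps differed by -1.034 (exact permutation p 0.0286), which argues against the animals of that batch as the whole source. Handling of tissue or cells stays open: unseen heat shock genes were lower by as much or more (-1.661), all 4 populations moved together, and no handling record crosses the statuses, so infection and handling cannot be told apart. Infection itself may lower these genes and stays among the open explanations, untested.

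The second pattern is the higher level of B cell transcripts (IGJ, CD79A and CR2) in TFH than in TREG of uninfected animals. B cells or their RNA in the TFH libraries stay open: CD79B, MS4A1 and CD22 had a median paired difference of -0.568, but each is listed at 0 in at least 3 of 5 libraries of both populations, so they decide nothing. CD74 (65.6 FPKM in TFH, 304 in TREG, -2.357) and MAMU-DRA (7.77 and 23.2 FPKM, -1.042) were lower in TFH. Bulk CD4 cells had about as much of both as TREG (312 and 24.0 FPKM). The lower level in TFH therefore need not reflect B cells and decides nothing. The 3 transcripts were not confined to TFH: CR2 was at 50.5 FPKM in bulk CD4 and 54.5 in TFH, and CD79A at 37.4 in TFR and 28.5 in TFH. How much of each transcript B cells would bring is not given in the sources used here, so these values exclude no share of B cells. Expression of these genes by TFH cells may explain the pattern and was not tested.

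The third pattern is that infection called 25 genes in TFR and 452 in TFH. It depends on the fit: array weights gave 253 and 633, and the fit of all 40 libraries with the animal as a random block gave more in TFR (423) than in TFH (226). That fit takes 1 spread per gene over all groups, so the 423 does not rest on the spread in TFR alone. In the separate fits the median SE over genes was 0.892 in TFR and 0.572 in TFH, so fewer calls go with the wider spread in TFR. Over 398 genes called in TREG the mean signed effect was 1.67 in TFR and 1.69 in TFH. The difference was -0.018 (exact permutation p 0.889) and the ratio 0.989. This argues against a smaller infection effect in TFR for these genes only. They were picked by their call in TREG of the same animals, which favours genes that move in every population. Genes that infection changes in TFH but not in TREG are not among them. The sparse libraries stay open as a possible source: without them TFR gave 161 genes, 54.6% of the 295 called in TFH without the same 2 animals, which lies between what was set for and against them. A difference in the number of cells sorted was not tested.

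In 727 groups of 5 values, 62 held a value far from the other 4 by Dixon's test, where chance flags about 1 in 20 groups, or 36. The numbers below are the gap to the nearest value as a share of the group's range. The number of genes at FPKM 1 or more set apart the sparse library in uninfected TFR (0.805) and in infected TFR (0.738). The hypoxia score had a far animal in uninfected CD4 (0.759), infected TFR (0.859) and infected CD4 (0.729).

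Among differences between populations within an animal, 1 animal stood apart for CTLA4 between TFR and TFH (0.76) and for CD69 (0.886), IER5 (0.856) and CXCR6 (0.753) between TFR and TREG in uninfected animals. The same held for IGFBP4 (0.714) and TNFSF10 (0.736) between TFH and TREG, and for CYB5R1 (0.802) and ADORA2A (0.762) between TFH and CD4. In infected animals these were BTLA (0.8) and TNFRSF1B (0.767) between TFR and TFH, PDCD1 (0.73) between TFR and TREG, and C10orf116 (0.837) and AZGP1 (0.747) between TFH and TREG.

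Single libraries stood apart in infected TFR for PHGDH (0.876), PFKFB4 (0.959), BNIP3 (1.0), RPS27L (0.722), ICOS (0.774), IL21 (0.829) and PRDM1 (0.792). In uninfected TFR this was so for PHGDH (0.847), RASGRP2 (1.0), NKG7 (1.0), UBE2C (0.846) and GAPDH (0.777). In infected TFH it was so for CDC20 (0.92), ANKRD37 (0.742), SLC2A3 (0.713), BNIP3 (1.0) and MCM3 (0.725), and in uninfected TFH for ABHD12B (1.0) and BNIP3 (0.723). A share of 1.0 means that the other 4 libraries are equal.

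In uninfected TREG the genes with a far library were ACY1 (1.0), RAB37 (1.0), CD79A (0.873), GAL (1.0), N6AMT2 (1.0), AURKA (0.789), TRAF1 (0.808) and RPL10 (0.735). In infected TREG they were HILPDA (0.765), PFKFB4 (1.0), IL4R (0.74) and CD4 (0.832). In uninfected CD4 cells they were CDKN3 (0.872), FAM212A (1.0), OGG1 (0.938), TMEM101 (1.0), SOAT2 (1.0), NSUN3 (1.0), HILPDA (0.748), PLK1 (0.79), CCNB2 (0.891) and CXCR5 (0.811). In infected CD4 cells they were HILPDA (0.711), AURKB (0.759) and FOXP3 (0.836).

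The test of the difference of the infection effect called 2 lists, 0 of whose genes were called over all genes, and with the estimated correlation none of these calls passed (adjusted p 0.480, 0.440 and 0.0989). At the preset correlation Th1 and cytotoxic genes moved higher in TFR than in TFH (median 1.047, adjusted p 0.0025) and than in TREG (median 0.656, adjusted p 0.0359), and Th17 and Th2 genes than in TREG (median 0.9, adjusted p 0.0022).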

How the results depend on the processing

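The fits without the sparse libraries, without the 2 animals lacking the shared read steps, without both, and with the read-step batch as a term were chosen only after the results had been seen. The counts below are called genes. Where a count is not given for a setting, it stayed within 1.5 times the reported one. Except where stated, the cause was not tested.

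A pseudocount of 0.1 gave 65 for TFH against TREG and 64 for TFH against CD4, 0 for TREG against CD4, and in infected animals 6 for TFR against TREG and 22 for TFH against TREG. Infection gave 13 in TFR, 273 in TFH, 2.5e+02 in TREG (115 higher and 137 lower) and 162 in CD4. Without a filter there were 71 for TFH against TREG, 43 for TFH against CD4, and for infection 14, 229, 169 and 123 in the same order, with more genes tested. Quantile normalization gave 29 for TFR against TREG and 72 for TFH against TREG in infected animals, 78 for infection in TFR, and 1 for the difference between TFR and TFH. A filter of 5 FPKM and median-ratio scaling kept every count within 1.5 times.

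Array weights gave 215 for TFH against TREG and 161 for TFH against CD4, and in infected animals 6, 51 and 175 for TFR against TFH, TFR against TREG and TFH against TREG. They gave 253 for infection in TFR, 543 in CD4, and 1 for each difference of the infection effect. The 40 libraries in 1 fit with the animal as a random block gave 423, 226, 246 and 468 for infection in TFR, TFH, TREG and CD4.

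Dropping the animal block gave 67 for TFR against TREG, 55 for TFH against TREG, 92 for TFR against CD4 and 26 for TFH against CD4, and 1, 4 and 12 in infected animals. With only the populations compared in the fit, and so fewer libraries, the counts were 3, 8, 68, 30, 44 and 6 for TFR against TFH, TFR against TREG, TFH against TREG, TFR against CD4, TFH against CD4 and TREG against CD4. In infected animals they were 0, 0 and 95. Every comparison with TFR fell, while those without TFR fell (107 to 68, 105 to 44) or rose (2 to 6, 44 to 95). The main fit takes 1 spread per gene over the 4 populations, so its TFR counts do not rest on the spread in TFR alone. In the separate infection fits the median SE was 0.892 in TFR and 0.572 to 0.703 in the other populations.

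Without the sparse libraries the counts were 179 for TFH against TREG, 191 for TFH against CD4 and 5 for TREG against CD4, in infected animals 20 for TFR against TREG and 103 for TFH against TREG, and 161 for infection in TFR. Without the 2 animals lacking read steps, and so with fewer samples, they were 86, 64, 73 and 17 for TFR against TREG, TFH against TREG, TFR against CD4 and TFH against CD4. In infected animals they were 1, 5 and 16, and infection gave 5, 173, 139 and 125. Leaving out both gave 75, 171 and 122 for TFR against TREG, TFH against TREG and TFR against CD4, 0 for TFR against TFH in infected animals, and 173, 139 and 125 for infection in TFH, TREG and CD4. The batch as a term kept infection at 32, 464, 470 and 360.

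Leaving out 1 animal at a time gave 4 to 7 genes for TFR against TFH, 35 to 123 for TFR against TREG, 29 to 99 for TFH against TREG, 60 to 159 for TFR against CD4, 13 to 62 for TFH against CD4 and 0 to 4 for TREG against CD4. In infected animals it gave 0 to 5, 0 to 31 and 5 to 88. Infection gave 11 to 96 in TFR, 211 to 572 in TFH, 154 to 545 in TREG and 104 to 306 in CD4, and the differences of the infection effect 0 to 2 and 0 to 1. The highest infection counts in TFR, TREG and CD4 came without infected replicate 4, whose TREG and CD4 libraries are not sparse. Of the 504 named pairs, 256 were called in the main fits. With an animal left out 139 to 220 were counted as called, which can include pairs not called in the main fits. An infection pair was counted for a replicate number only if it was called without that replicate of each status. The range is therefore not the number of the 256 calls that stayed.

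The difference in TFR position ran from -0.157 to 0.122 when 1 animal was left out, with its sign changed without infected replicate 1 (0.054) or 3 (0.122), and was 0.006 without the 2 animals lacking read steps. The median of single-gene ratios in each animal, fixed in advance, gave a larger difference of -0.198 (exact permutation p 0.143). The difference was not past the threshold under any setting. In each setting the genes were chosen separately for the 2 statuses, so this does not show an equal position.

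With the estimated correlation 37 of 107 list calls held and 70 did not. The pseudocount of 0.1 ended 1 list call and quantile normalization 6, and under the latter the ribosomal protein list changed direction between TFR and TFH in infected animals (adjusted p 0.9034).

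Of the 504 named pairs, the pseudocount of 0.1 kept 443, made 1 called, ended 59 and reversed 1, and quantile normalization kept 460, made 24 called, ended 16 and reversed 4. No reversed pair was called. Quantile normalization reversed ICOS between TFR and TREG (-0.094) and, for infection, IL2RA in TFH (-0.4), IFIT3 in TREG (-0.107, and -0.003 with the pseudocount of 0.1) and CXCR5 in CD4 (-0.101). Leaving out 1 animal reversed 46 of the values. In uninfected animals the reversed genes ran from -0.006 to 0.54 (CXCR5, TFR against TFH), from -0.45 to 0.111 (XBP1), -1.11 to 0.021 (IL2RA) and -0.056 to 0.152 (ICOS) between TFR and TREG, and from -0.31 to 0.501 (XBP1), -0.038 to 0.255 (CTLA4) and -0.124 to 0.083 (CD4) between TFH and TREG. For infection in TFR they ran from -0.79 to 0.249 (CTLA4), -0.381 to 0.999 (CXCR5), -1.394 to 0.555 (IL21) and -1.695 to 0.117 (IFIT3), and in TFH from -0.45 to 0.685 (IL2RA) and -0.633 to 1.57 (ISG15). In TREG they ran from -0.017 to 0.621 (FOXP3), -0.716 to 0.697 (ISG15) and -0.339 to 0.37 (IFIT3), and in CD4 from -0.188 to 0.415 (CTLA4), -0.223 to 0.529 (CXCR5), -0.858 to 0.454 (IL21) and -1.278 to 0.077 (ISG15).

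Depth in reads is unknown, so what it limits was not computed. The simulated data put the limit for infection in TFR at 38.2% of changes of 3 on the log2 scale recovered, against 90.9% in TFH.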

Other observations

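The regroupings of libraries for each count of called genes were chosen only after the counts had been seen. The regrouping of animals for the genes shared between populations was fixed before its result was seen.

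Beyond the hypoxia and heat shock genes, the 91 genes shared by TFH, TREG and CD4 included the histone genes HIST1H2AC, HIST2H2BE and HIST1H4H and the sterol gene SC5DL, all lower in infected animals, and DTX1, P2RX7 and TBC1D10C, all higher. These genes were picked after their values were seen. HIST1H2AC differed by -3.59 in TFH and -3.48 in TREG, and P2RX7 by 2.68 and 3.48. Of 100 regroupings of the 10 animals, the real one included, 1 gave as many shared genes, with 91 for the real grouping and 0 for the highest other.

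Each animal gave every population, so the populations were exchanged within animals, which gives 16 splits per comparison, too few for a share under 0.05. In uninfected animals the real count and the highest other were 7 and 1 for TFR against TFH, 144 and 0 for TFR against TREG, 107 and 0 for TFH against TREG, 201 and 0 for TFR against CD4, 105 and 0 for TFH against CD4, and 2 and 0 for TREG against CD4. In infected animals they were 2 and 2, 11 and 0, and 44 and 0 for TFR against TFH, TFR against TREG and TFH against TREG. In the first of these 2 of the 16 splits gave as many genes, and elsewhere only the real one did (1 of 16). In 100 splits that ignore the animals, the highest others were 2, 2, 1, 5, 5 and 1 in uninfected and 1, 16 and 1 in infected animals. Those splits place both libraries of some animals in one group and so are no fair comparison with the real one.

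For each infection count, 100 splits of the same libraries into groups of the same sizes were drawn, the real one included. The real count and the highest other were 452 and 77 in TFH, 398 and 71 in TREG and 283 and 3 in CD4. Only the real split (1 of 100) gave as many in each, so regrouping the animals at random rarely gives such counts. The splits cannot tell infection from any other difference between the infected and the uninfected animals. In TFR they were 25 and 24, also with 1 split of 100. The margin in TFR is 1 gene, not every possible split was drawn, and leaving out 1 animal gave 11 to 96. For the differences of the infection effect the real counts were 0 and the highest others 1 and 4. All 100 splits give at least 0, so these splits decide nothing.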
